A study of Arabidopsis thaliana with 16 samples.

How the data were processed

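Total RNA from the 3rd or 4th leaf of Arabidopsis plants grown in soil, harvested 6 h after light-on, was labelled with Cy3 and hybridised to 16 Agilent arrays, per the labels' protocols. The labels name 2 independent biological samples for each of 8 groups, Col and nore1-1 at ages labelled 12, 16, 20 and 24. Per the file headers, each slide held the 4 ages of 1 genotype and replicate, and replicate 1 was scanned on another day than replicate 2. Position on the slide therefore followed age, and slide followed genotype, so neither can be separated from the groups by the design.

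The signal intensity of each spot had been background-subtracted and detrended within the array by Agilent Feature Extraction 11.5.1.1, per the file headers, without normalization between arrays. Median spot and local background intensity were also taken from the deposited scanner files. Deposited by the authors was also a log2 value per gene and array for 21569 genes, from 4.66 to 18.5, with column medians between 9.15 and 9.21, and how it was normalized is not stated in the labels. On 11234 genes its differences between arrays correlated with those of the scanner values at 0.980, with a slope of 0.851.

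Each array had 45220 spots, of which 1417 were controls, and 43603 distinct other probes. Of these 34348 were matched to 1 locus through the annotation columns of the files, for 25410 loci, and 9255 were not and were tested apart. Gene symbols and neighbours, and nothing else, came from a reference annotation of assembly TAIR10.1, since the build named in the files differs. For the 6946 loci with more than 1 probe the probe of highest mean signal was used, and 56 probes with an outlier-marked spot on an array were left out. Among the genes named by rule, 34 of 37 pairs of gene and comparison with several probes had all probes in the same direction. A gene was tested where its probe was well above background on both arrays of at least 1 group, which left 20531 genes and excluded 4879. Signal over background limits the rest, and small surrogate values stand in for signals not above background. Spike-in slopes lay between 0.950 and 1.02.

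Signals were put on the log2 scale and the 75th percentile of each array was subtracted. Group means for the 8 groups were fitted with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with data.table (version 1.17.8) and jsonlite 2.0.0. The fit had 8 residual degrees of freedom and 2.23 prior degrees of freedom. Contrasts were nore1-1 against Col at each age and averaged over ages, 24 against 12 days in each genotype, and the difference between these changes. P values were adjusted by Benjamini-Hochberg within a contrast, and an adjusted p under 0.05 was a call. Figures were drawn with python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.

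Where a group was not well above background on either array, its fold change was given as a bound. This was the mean of the bright group over the mean of the dim group, with each dim value raised to the lowest signal found among probes well above background on that array. A fold change is given as partly measured where 1 of the 2 arrays of a group was above background. For the average and the difference between changes, some values are also given with each signal not well above background raised to that lowest signal.

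The 30 gene lists covered SAUL1 and linked immune receptors, salicylic acid, pathogenesis-related genes, immune receptors, camalexin and indole glucosinolates, aliphatic glucosinolates, senescence transcription factors, senescence-associated genes, chlorophyll breakdown and synthesis, light-harvesting antenna, photosystem and carbon fixation, autophagy and nitrogen remobilisation. The others were jasmonate, ethylene, abscisic acid, cytokinin, endoplasmic reticulum chaperones, heat shock, oxidative stress, flavonoids, the clock, flowering and phase change, cell division, and markers of guard cells, epidermis and trichomes, phloem and xylem, flower organs and roots. Of 418 members, 403 matched by symbol, 11 had no symbol there, 4 were left out because another symbol is given, and 405 were measured. Lists with at least 3 measured genes were tested with camera of limma at a preset correlation between genes of 0.01, and again with an estimated correlation. Members were also adjusted over the list alone.

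Genes were named by a rule. SAUL1 was given in every array. For the average, the 10 highest and 10 lowest called genes with the same sign at all 4 ages were taken, and for the other contrasts the 5 highest and 5 lowest called genes whose replicates did not overlap, except for the difference between changes, where any called gene counted. The rule was repeated among genes well above background on every array. Up to 4 members per list with the largest change and 14 immune and senescence genes were added. Lists, naming rule, the 8 contrasts and the alternatives were fixed before the data were examined. Values within each scan day, the contrasts of 16 and 20 with 12 days, signals raised in the average and in the difference, the probes without a locus and the runs of neighbouring genes were chosen after the data were seen.

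Alternatives were quantile and median scaling, normexp background correction (offset 50) before 75th percentile or quantile scaling, no filter, a filter on all 16 arrays, the mean of probes, the authors' table, eBayes with trend and robust, only the arrays of the groups compared, replicate number (equal to scan day) as a block, slide as a fixed or random block (correlation within a slide 0.230), and each array left out. Mean spot signal, planned for normexp, is not in the files used, and the median was used instead. For lists the fry test was added. For the comparison of genotype and age effects, 100 sets of unchanged groups were simulated.

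The steps were tested on simulated data of 20531 genes with 200 changed. At 20 days 0% of 2-fold and 73.5% of 4-fold changes were recovered, with 11 unchanged genes called at 4-fold. For the average 73% and 94% were recovered, with 6 and 7 unchanged genes called, and for the difference between changes 0% and 44.5%, with 0 and 3. Benjamini-Hochberg is stricter where few genes change. In the data 2268 to 4742 passed in these contrasts, so these shares need not hold there. Of 30 simulated lists the 5 raised ones were recovered and 0 of the others were called. The simulated genes varied independently, so this does not test the preset correlation on lists whose genes vary together.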

Results

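Gene expression was measured in the 3rd or 4th leaf of Col (wild type) and nore1-1 at 4 ages labelled 12, 16, 20 and 24 days. From background knowledge, nore1-1 carries a mutation in SAUL1 (AT1G20780), a U-box ubiquitin ligase that restrains immune signalling and leaf senescence. Each of the 8 groups had 2 independent biological samples per the labels, each hybridised to 1 single-colour array. Between 30422 and 33839 of the 43603 probes were well above background on an array, a share of 69.8% to 77.6%. The 75th percentile of the signal ran from 945 to 2216, and 0 spots were saturated on the array with the most. Replicate arrays of a group correlated at 0.970 to 0.987 across genes. The number of arrays limits the precision of all comparisons. The first principal component held 70.7% of the variance and followed age. On it the Col arrays moved from -107 and -149 at 12 days to 86.5 and 33.8 at 24 days, and the nore1-1 arrays from -125 and -157 to 165 and 211. In the tests 20531 genes entered. All fold changes are on the log2 scale with their standard error (SE), with n = 2 arrays per group, and all adjusted p values come from limma.

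SAUL1 was measured on all 16 arrays and did not pass the test in any comparison. Relative to the 75th percentile of each array, its log2 signal in Col for replicates 1 and 2 was -0.24 and 0.13 at 12 days, -0.08 and 0.46 at 16 days, -0.40 and 0.42 at 20 days, and -0.34 and -0.08 at 24 days. For nore1-1 the values were -0.11 and 0.09 at 12 days, -0.13 and 0.29 at 16 days, 0.37 and 0.66 at 20 days, and 0.08 and 0.57 at 24 days. Group means were -0.05 ± 0.26 (SD, n = 2) in Col and -0.01 ± 0.14 in nore1-1 at 12 days, and -0.21 ± 0.18 and 0.33 ± 0.35 at 24 days. The log2 difference averaged over the 4 ages was 0.24 ± 0.16 (SE, adjusted p = 0.289). Where the SAUL1 probe lies relative to the mutation is not known, so its signal does not check the genotype labels.

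**Figure D1:**
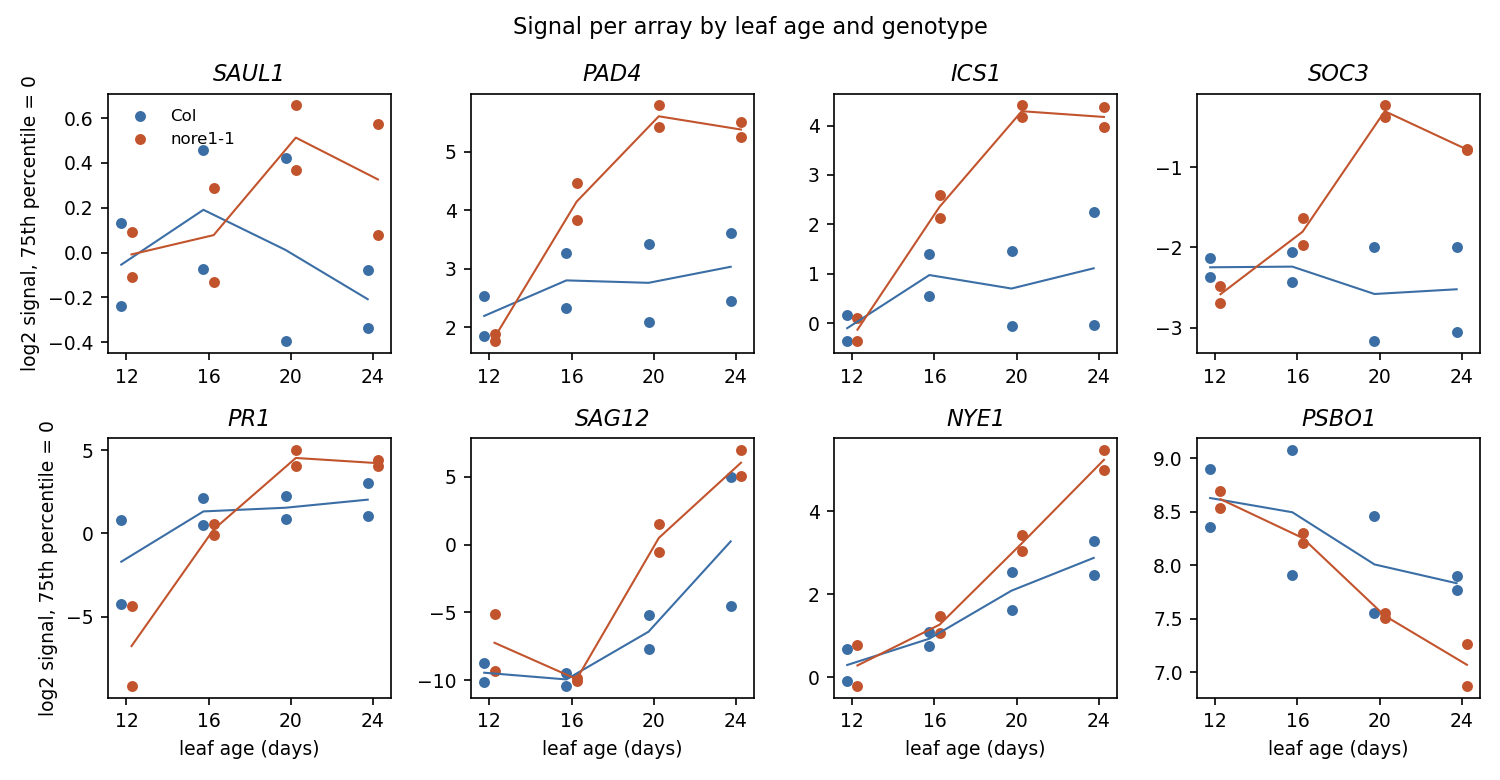
Log2 signal relative to each array's 75th percentile (y axis) against leaf age in days (x axis) for SAUL1, PAD4, ICS1, SOC3, PR1, SAG12, NYE1 and PSBO1; points are arrays, lines join group means of 2 arrays, and colours give the genotype. PAD4 was higher in nore1-1 by a log2 fold change of 2.85 at 20 days and 2.35 at 24 days, while SAUL1 did not pass the test at any age.

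The comparison of the genotypes at 12 days asked how the youngest leaves differed. Of 20531 genes, 5 passed the test, 2 higher and 3 lower in nore1-1, and all 5 lie on chromosome 3. The gene AT3G55920 was not well above background in Col and was at least 206-fold higher in nore1-1 (log2 8.13 ± 0.44, adjusted p = 3.43e-05). AT3G05170 was higher by 5.12 ± 0.25 (adjusted p = 2.34e-05). Lower in nore1-1 were AT3G28899 at -5.12 ± 0.42 (adjusted p = 0.000965), AT3G56210 at -3.35 ± 0.33 (adjusted p = 0.00493) and AT3G07170 at -2.43 ± 0.14 (adjusted p = 3.82e-05). AT3G56210 rests on 1 of its 3 probes: 2 of them were lower, and in the authors' table, which combines probes, its log2 difference was 0.23. Of the immune and senescence genes named in advance none passed: the marker of salicylic acid defence PR1 differed by -5.06 ± 1.7, measured on 1 of 2 nore1-1 arrays (adjusted p = 1.00).

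Of the 30 gene lists, 11 passed at 12 days while 0 of their members were called singly by limma, where 571 of all genes had an unadjusted p under 0.05. This is a smaller share than the 0.05 that unchanged genes would give on average. Pathogenesis-related genes had a median of -1.07 (adjusted p = 5.03e-05), abscisic acid genes -0.34 (adjusted p = 5.55e-05), and salicylic acid genes -0.38 (adjusted p = 0.000110). Immune receptors had a median of -0.22 (adjusted p = 0.00286), endoplasmic reticulum chaperones -0.45 (adjusted p = 0.00535), jasmonate genes -0.23 (adjusted p = 0.0140), clock genes -0.54 (adjusted p = 0.0283) and senescence transcription factors -0.27 (adjusted p = 0.0429). Higher medians were found for flower organ markers at 0.78 (adjusted p = 0.00508), chlorophyll synthesis at 0.23 (adjusted p = 0.00648) and photosystem genes at 0.11 (adjusted p = 0.0281). With an estimated correlation the adjusted p was 0.286 for flower organ markers, 0.898 for photosystem genes and 0.776 for the other 9 lists. Adjusted over the list alone, 0 members of these lists passed. Within each scan day 10 of the 11 medians kept their sign, while chaperones had -1.02 on day 1 and 0.18 on day 2. The medians on days 1 and 2 were over 1.5 times apart for 8 of 11 lists: pathogenesis-related genes -1.46 and -0.42, salicylic acid -0.47 and -0.16, senescence transcription factors -0.13 and -0.33, and jasmonate -0.17 and -0.31. The rest of these were receptors -0.29 and -0.16, abscisic acid -0.25 and -0.43, photosystem genes 0.11 and 0.18, and the clock -0.59 and -0.37. Without Col at 12 days replicate 1, 1 of the 5 called genes no longer passed (adjusted p = 0.0851), and without nore1-1 at 12 days replicate 2 also 1 (adjusted p = 0.0525). With scan day as a block 8 genes passed.

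At 16 days 8 genes passed, 5 higher and 3 lower in nore1-1. AT3G55910 was at least 8.43-fold higher (log2 5.41 ± 0.45, adjusted p = 0.000907), and AT3G05170 was higher by 5.10 ± 0.25 (adjusted p = 2.42e-05). AT3G55920 was higher by 7.75 ± 0.44 (adjusted p = 4.09e-05), with 1 of the 2 Col arrays well above background. AT2G29220 was at least 3.75-fold higher (log2 3.23 ± 0.40, adjusted p = 0.0261) and RTFL11 at least 1.01-fold higher (log2 1.83 ± 0.25, adjusted p = 0.0498), the latter well above background on 1 of the 2 nore1-1 arrays. AT3G28899 at -5.12 ± 0.42, AT3G56210 at -3.14 ± 0.33 and AT3G07170 at -2.42 ± 0.14 were lower (adjusted p = 0.000907, 0.00736 and 4.09e-05), and AT3G56210 differed by 0.37 in the authors' table. Leaving out any 1 array other than the Col arrays at 20 days ended at least 1 of the 8 calls. Without Col at 16 days replicate 1 or nore1-1 at 16 days replicate 2 the count was 5, and without Col replicate 2 or nore1-1 replicate 1 at that age 3 calls ended (adjusted p up to 0.652 over these 4 arrays). Of the arrays of other groups, each nore1-1 array at 12, 20 and 24 days ended 2 calls (adjusted p up to 0.0974) and each Col array at 12 and 24 days ended 1 (adjusted p up to 0.0995). Background correction with normexp before the same scaling gave 5886 calls, 5820 higher and 66 lower, and moved the median of all genes by 0.28.

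At 16 days 8 lists passed with 0 members called by limma, where 528 of all genes had an unadjusted p under 0.05, and 0 members passed adjusted over the list alone. The 528 genes were again a smaller share than 0.05. Photosystem genes had a median of -0.22 (adjusted p = 7.06e-05), jasmonate genes -0.36 (adjusted p = 0.000536), aliphatic glucosinolate genes -1.01 (adjusted p = 0.00849), antenna genes -0.21 (adjusted p = 0.0268), chlorophyll synthesis -0.16 (adjusted p = 0.0387) and cell division -0.31 (adjusted p = 0.0387). Senescence-associated genes had a median of 0.46 (adjusted p = 0.0297) and salicylic acid genes 0.13 (adjusted p = 0.0399). With an estimated correlation the adjusted p was 0.826 for each of the 8 lists. The medians of salicylic acid genes and of cell division changed sign with normexp and 75th percentile scaling, to -0.01 and 1.68. On scan day 2 the antenna and photosystem medians were 0.12 and 0.07, against -0.58 and -0.52 on day 1, while the other 6 kept their sign on both days. For 3 of 8 lists the medians of days 1 and 2 were over 1.5 times apart: salicylic acid 0.46 and 0.01, jasmonate -0.51 and -0.17, and senescence-associated genes 0.22 and 0.48. With scan day as a block, the salicylic acid list no longer passed (adjusted p = 0.0977).

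At 20 days ICS1, the synthase of the salicylic acid pathway, was 12.1-fold higher in nore1-1 than in Col (log2 3.59 ± 0.68, adjusted p = 0.0148). PAD4 and EDS1, lipase-like proteins that relay signals from immune receptors, were 7.20-fold (log2 2.85 ± 0.51, adjusted p = 0.0132) and 4.07-fold higher (log2 2.02 ± 0.43, adjusted p = 0.0215). The receptor genes SOC3 and CHS1, neighbours on chromosome 1, were higher by 2.28 ± 0.39 (adjusted p = 0.0118) and 1.85 ± 0.49 (adjusted p = 0.0392). PR1 differed by 2.99 ± 1.7 (adjusted p = 0.264) and the senescence protease gene SAG12 by 6.91 ± 2.46 (adjusted p = 0.0933), neither past the test.

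In all 2268 genes passed at 20 days, 918 higher and 1350 lower, of which 1805 changed at least 2-fold. The highest was AT3G55910, at least 171-fold higher (log2 9.75 ± 0.45, adjusted p = 6.88e-06), followed by AT3G55920 at 7.18 ± 0.44, measured on 1 of 2 Col arrays (adjusted p = 5.90e-05), AT4G36850 at 6.03 ± 0.90 (adjusted p = 0.00707) and AT3G05170 at 5.68 ± 0.25 (adjusted p = 6.88e-06). AT1G67635 was higher by 5.58 ± 0.68 (adjusted p = 0.00450), the gibberellin-inactivating oxidase gene GA2OX2 by 5.2 ± 0.92 (adjusted p = 0.0124) and AT5G52730 by 5.11 ± 1.02 (adjusted p = 0.0174). The plant defensins PDF1.2, PDF1.2b, PDF1.2c and PDF1.3, markers of jasmonate and ethylene signalling, were lower by -5.65 ± 1.39, -5.16 ± 1.23, -4.90 ± 1.25 and -4.86 ± 1.18 (adjusted p = 0.0316, 0.0286, 0.0361 and 0.0309). UMAMIT36, of an amino acid transporter family, was lower by -5.14 ± 0.78 (adjusted p = 0.00742). Near-identical copies such as the PDF1.2 family, GSTF6 and GSTF7, the LHCB1 genes and the RBCS genes can share probe sequence and are uncertain one by one.

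Of the gene lists, 10 passed at 20 days. Among 25 salicylic acid genes 9 rose, such as PBS3 at 3.34 ± 0.82 (adjusted p = 0.0319) and the transporter gene EDS5 at 2.89 ± 0.70 (adjusted p = 0.0308), and 16 did not pass. Their median was 1.32 (adjusted p = 5.63e-08, and adjusted p = 0.625 with an estimated correlation), and 15 passed adjusted over the list alone. Of 13 pathogenesis-related and other defence output genes 3 rose, BAP1 by 3.74 ± 0.59 (adjusted p = 0.00917) and AIG1 by 3.54 ± 0.96 (adjusted p = 0.0431) among them, while PR1 did not pass. The list median was 1.22 (adjusted p = 0.000334, and 0.625 with an estimated correlation), with 4 adjusted over the list alone. The list of SAUL1 and linked receptors held SAUL1, SOC3, CHS1, TN2 and PUB43, which is not a receptor gene. Of these 5, 2 were higher, 3 adjusted over the list alone. The median was 1.85 (adjusted p = 0.00436, and 0.625 with an estimated correlation). Of 18 immune receptors 3 rose, for example ADR1 by 1.65 ± 0.41 (adjusted p = 0.0320) and LYK5 by 1.09 ± 0.30 (adjusted p = 0.0475). Adjusted over the list alone 9 rose and 2 fell, with a median of 0.59 (adjusted p = 0.00459, and 0.625 with an estimated correlation).

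Senescence-associated genes at 20 days had 3 of 10 higher, such as the sugar transporter gene SWEET15 at 4.56 ± 0.87 (adjusted p = 0.0155), and 5 adjusted over the list alone. Their median was 1.65 (adjusted p = 0.000897, and 0.625 with an estimated correlation). Aliphatic glucosinolate synthesis, which makes defence compounds against herbivores, had 2 of 10 genes lower, and all 10 adjusted over the list alone. MAM3 was at -2.37 ± 0.58 (adjusted p = 0.0319) and the regulator MYB28 at -2.13 ± 0.52 (adjusted p = 0.0309), with a list median of -2.50 (adjusted p = 0.000172, and 0.625 with an estimated correlation). Photosystem and carbon fixation genes had 3 of 37 lower, including FBA1 at -1.52 ± 0.39 (adjusted p = 0.0373), 0 adjusted over the list alone, and a median of -0.63 (adjusted p = 2.27e-06, and 0.625 with an estimated correlation). Antenna genes had 0 of 21 called and 0 adjusted over the list alone by limma, with a median of -0.65 (adjusted p = 0.00125, and 0.655 with an estimated correlation). For chaperones of the endoplasmic reticulum 0 of 13 passed, also 0 adjusted over the list alone, and the median was 1.31 (adjusted p = 0.000701, and 0.625 with an estimated correlation). Autophagy had 1 of 22 higher, also 1 adjusted over the list alone, ATG1A at 1.12 ± 0.25 (adjusted p = 0.0244), and a median of 0.23 (adjusted p = 0.0468, and 0.625 with an estimated correlation). All 10 medians kept their sign on both scan days, and across all genes the differences of the 2 days correlated at 0.686. Day 1 and day 2 medians differed by over 1.5 times for 8 of 10 lists: pathogenesis-related genes 1.86 and 0.74, aliphatic glucosinolates -3.57 and -1.51, chaperones 1.85 and 0.83, and salicylic acid 1.85 and 0.83. The rest of these were SAUL1 and linked receptors 2.49 and 1.22, receptors 0.71 and 0.37, antenna genes -0.76 and -0.44, and senescence-associated genes 1.91 and 1.15.

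The count at 20 days rested on single arrays: it was 78 without nore1-1 at 20 days replicate 1, 119 without Col replicate 1, 549 without nore1-1 replicate 2 and 1422 without Col replicate 2. Of the 42 named genes called at 20 days, these arrays ended 37, 36, 33 and 18 calls, and each array of another group at most 9 (adjusted p up to 0.0721). PAD4 had an adjusted p of 0.0771 without nore1-1 replicate 1, 0.101 without Col replicate 1 and 0.0609 without nore1-1 replicate 2, and over all alternatives it lay between 0.00233 and 0.101. With normexp and 75th percentile scaling 904 genes passed, 3723 with scan day as a block, and 3 with only the arrays of the groups compared. Median scaling moved the median of all genes by 0.12.

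**Figure D2:**
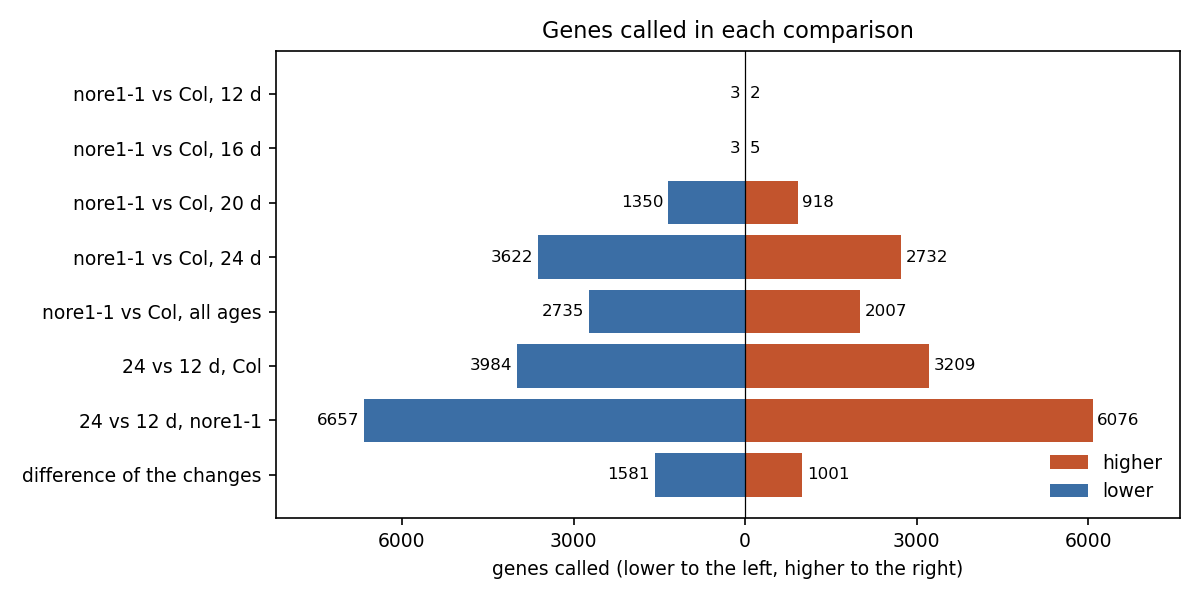
Number of genes past an adjusted p of 0.05 (x axis) in each comparison (y axis). Bars to the right give genes higher in nore1-1, or with age, and bars to the left give genes lower. The genotype comparison called 5 genes at 12 days, 8 at 16 days, 2268 at 20 days and 6354 at 24 days.

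At 24 days the polygalacturonase gene PGAZAT, of a family that loosens cell walls at abscission, was 129-fold higher in nore1-1 than in Col (log2 7.01 ± 1.36, adjusted p = 0.00517), and ADPG1 of the same family was higher by 7.86 ± 1.57, measured on 1 of 2 Col arrays (adjusted p = 0.00579). DIN2, a glucosidase gene induced in darkness, was 156-fold higher (log2 7.28 ± 1.12, adjusted p = 0.00227), and BFN1, a nuclease gene of senescence, 55.3-fold higher (log2 5.79 ± 1.09, adjusted p = 0.00452). NYE1, which starts chlorophyll breakdown, was 5.14-fold higher (log2 2.36 ± 0.45, adjusted p = 0.00462). PAD4 at 2.35 ± 0.51 (adjusted p = 0.00823), ICS1 at 3.07 ± 0.68 (adjusted p = 0.00860), EDS1 at 1.38 ± 0.43 (adjusted p = 0.0347), SOC3 at 1.74 ± 0.39 (adjusted p = 0.00929) and the receptor gene TN2 at 3.49 ± 0.91 (adjusted p = 0.0169) were higher as well.

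In all 6354 genes passed at 24 days, 2732 higher and 3622 lower, of which 4335 changed at least 2-fold. AT3G55910 was at least 637-fold higher (log2 11.64 ± 0.45, adjusted p = 1.15e-06). AT1G29100 at 8.38 ± 0.71 and scpl14 at 7.08 ± 0.86 were each measured on 1 of 2 Col arrays (adjusted p = 0.000352 and 0.00116), and AT2G34610 at 6.07 ± 0.79 and AT1G67635 at 5.92 ± 0.68 on all (adjusted p = 0.00135 and 0.00106). PDF1.2 at -6.82 ± 1.39 and AT5G22580 at -5.73 ± 0.77 were lower, each measured on 1 of 2 nore1-1 arrays (adjusted p = 0.00610 and 0.00140). AT1G52190 was lower by -6.41 ± 0.67 (adjusted p = 0.000869), AACT1 by -6.07 ± 0.96 (adjusted p = 0.00238), AT5G14920 by -5.72 ± 0.48 (adjusted p = 0.000352), AT3G28899 by -5.43 ± 0.42 (adjusted p = 0.000244) and the myrosinase-binding protein gene MBP1 by -5.12 ± 1.23 (adjusted p = 0.0121). Neither PR1 at 2.19 ± 1.7 (adjusted p = 0.353) nor SAG12 at 5.79 ± 2.46 (adjusted p = 0.0988) passed.

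Of 30 lists 10 passed at 24 days. Photosystem and carbon fixation genes fell in 28 of 37 cases, such as PSBQ2 at -1.81 ± 0.31 (adjusted p = 0.00303) and PSAL at -1.74 ± 0.33 (adjusted p = 0.00452), with 30 adjusted over the list alone. Their median was -1.17 (adjusted p = 6.40e-10, and 0.555 with an estimated correlation). Antenna genes fell in 10 of 21 cases, LHCB4.2 by -1.83 ± 0.41 (adjusted p = 0.00893) and LHCA2 by -1.71 ± 0.34 (adjusted p = 0.00540) among them, and 12 adjusted over the list alone. The antenna median was -1.28 (adjusted p = 0.000153, and 0.555 with an estimated correlation). Chlorophyll synthesis fell in 10 of 16 genes, also 10 adjusted over the list alone, for example PORB by -2.84 ± 0.58 (adjusted p = 0.00610) and CHLM by -1.94 ± 0.28 (adjusted p = 0.00177), with a median of -0.84 (adjusted p = 0.00119, and 0.555 with an estimated correlation). Aliphatic glucosinolate genes fell in 8 of 10 cases and in all 10 adjusted over the list alone, such as CYP79F1 by -3.37 ± 1.09 (adjusted p = 0.0399), with a median of -2.63 (adjusted p = 0.00195, and 0.555 with an estimated correlation). CYP79F1 itself was at -1.34 without nore1-1 replicate 2 and -5.39 without replicate 1, and passed in 13 of 28 alternatives (adjusted p 0.00169 to 0.284).

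Autophagy genes, which recycle cell contents, rose in 9 of 22 cases at 24 days, ATG8H by 2.84 ± 0.32 (adjusted p = 0.00105) and ATG7 by 2.41 ± 0.30 (adjusted p = 0.00126) among them. Adjusted over the list alone 13 rose, and the median was 0.68 (adjusted p = 1.72e-05, and 0.555 with an estimated correlation). Salicylic acid genes rose in 11 of 25 cases and 1 fell, 12 and 1 adjusted over the list alone, with CBP60G at 2.65 ± 0.53 (adjusted p = 0.00578) and a median of 1.38 (adjusted p = 7.49e-05, and 0.555 with an estimated correlation). Senescence transcription factors rose in 4 of 17 cases, also 4 adjusted over the list alone, with NAC055 at 2.73 ± 0.32 (adjusted p = 0.00107) and WRKY75 at 2.58 ± 0.71 (adjusted p = 0.0214). The list had a median of 0.87 (adjusted p = 0.00936, and 0.555 with an estimated correlation). Senescence-associated genes rose in 4 of 10 cases, also 4 adjusted over the list alone, with a median of 1.33 (adjusted p = 0.0179, and 0.555 with an estimated correlation). SOC3, TN2 and PUB43 of SAUL1 and linked receptors rose, 3 of 5 cases and 4 adjusted over the list alone. The list median was 1.32 (adjusted p = 0.0167, and 0.555 with an estimated correlation). Nitrogen remobilisation rose in 4 of 12 genes and fell in 2, 6 and 2 adjusted over the list alone, with GDH2 at 2.73 ± 0.46 (adjusted p = 0.00311) and GDH1 at -1.86 ± 0.40 (adjusted p = 0.00754). Its median was 1.25 (adjusted p = 0.0418, and 0.555 with an estimated correlation).

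The other 20 lists did not pass at 24 days, although members of many did. Ethylene genes had 4 of 17 higher and 3 lower, the synthase gene ACS7 at 5.64 ± 0.79 (adjusted p = 0.00162) against the regulator ORA59 at -3.34 ± 0.28 (adjusted p = 0.000352), with a list median of 0.03 (adjusted p = 0.940). Immune receptors had 6 of 18 higher and 2 lower, the flagellin receptor gene FLS2 lower by -2.64 ± 0.38 (adjusted p = 0.00183), with a median of 0.50 (adjusted p = 0.0946). Pathogenesis-related genes had 4 of 13 higher and 1 lower (median 0.74, adjusted p = 0.0635), oxidative stress 6 of 13 higher and 1 lower (1.16, adjusted p = 0.125), and heat shock 3 of 11 higher (0.53, adjusted p = 0.105). Chlorophyll breakdown had 4 of 13 higher and 2 lower (0.62, adjusted p = 0.202), camalexin and indole glucosinolates 1 of 11 higher and 2 lower (0.24, adjusted p = 0.940), and cytokinin response 1 of 11 higher and 4 lower (-1.04, adjusted p = 0.177). Jasmonate genes had 3 of 23 higher and 4 lower; their median was 0.05 and their mean -0.35 (adjusted p = 0.926). Abscisic acid genes had 4 of 19 higher and 5 lower (-0.27, adjusted p = 0.869), and flowering and phase change 4 of 9 lower (-1.03, adjusted p = 0.188), the regulator SPL3 at -1.70 ± 0.25 (adjusted p = 0.00181) among them. The clock had 2 of 11 lower (-0.38, adjusted p = 0.425), endoplasmic reticulum chaperones 1 of 13 higher (0.26, adjusted p = 0.417), flavonoid and anthocyanin synthesis 0 of 12 (1.1, adjusted p = 0.179) and cell division 0 of 8 (-0.46, adjusted p = 0.548). Markers of other cell types and organs also did not pass as lists: epidermis and trichomes with 3 of 6 lower (-1.24, adjusted p = 0.234), phloem and xylem with 1 of 10 lower (-0.55, adjusted p = 0.693), and roots with 0 of 3 (0.67, adjusted p = 0.236). Guard cells had 1 of 5 higher, a median of -0.14 and a mean of 0.08 (adjusted p = 0.967), and flower organs 1 of 4 higher and 1 lower (0.11, adjusted p = 0.926). Of all genes tested by limma, 8819 had an unadjusted p under 0.05.

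All 10 medians of the lists that passed kept their sign on both scan days at 24 days, and across all genes the differences of the 2 days correlated at 0.725. Medians of days 1 and 2 were over 1.5 times apart for 9 of 10 lists: nitrogen remobilisation 0.43 and 1.51, antenna genes -0.58 and -1.76, salicylic acid 0.72 and 1.98, photosystem genes -0.68 and -1.56, and chlorophyll synthesis -0.52 and -1.19. The rest of these were aliphatic glucosinolates -1.54 and -3.46, senescence transcription factors 0.68 and 1.31, senescence-associated genes 0.87 and 1.65, and SAUL1 and linked receptors 0.97 and 1.67. The median absolute log2 difference of called genes was 0.93 on day 1 and 1.69 on day 2. Of the 20 lists that did not pass, 6 medians had opposite signs on the 2 days, such as chaperones at -0.71 and 1.19, camalexin and indole glucosinolates at -0.33 and 1.04, phloem and xylem at 0.67 and -1.31, and epidermis and trichomes at 0.01 and -1.84. With scan day as a block, the nitrogen remobilisation list no longer passed (adjusted p = 0.0669). Without Col at 24 days replicate 2 the count was 2240 and without nore1-1 replicate 2 it was 2682. Of the 92 named genes called, 55 and 49 lost the call then, 17 and 13 without nore1-1 replicate 1 and Col replicate 1, and at most 9 without an array of another group (adjusted p up to 0.0659). PAD4 had an adjusted p of 0.0772 without Col replicate 2 and 0.0542 without nore1-1 replicate 2, and over all alternatives it lay between 0.00125 and 0.115. Median scaling called 3884 higher and 2552 lower against 2732 and 3622, and moved the median of all genes by 0.20. With normexp and 75th percentile scaling 3107 genes passed, and with only the arrays of the groups compared 1.

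**Figure D3:**
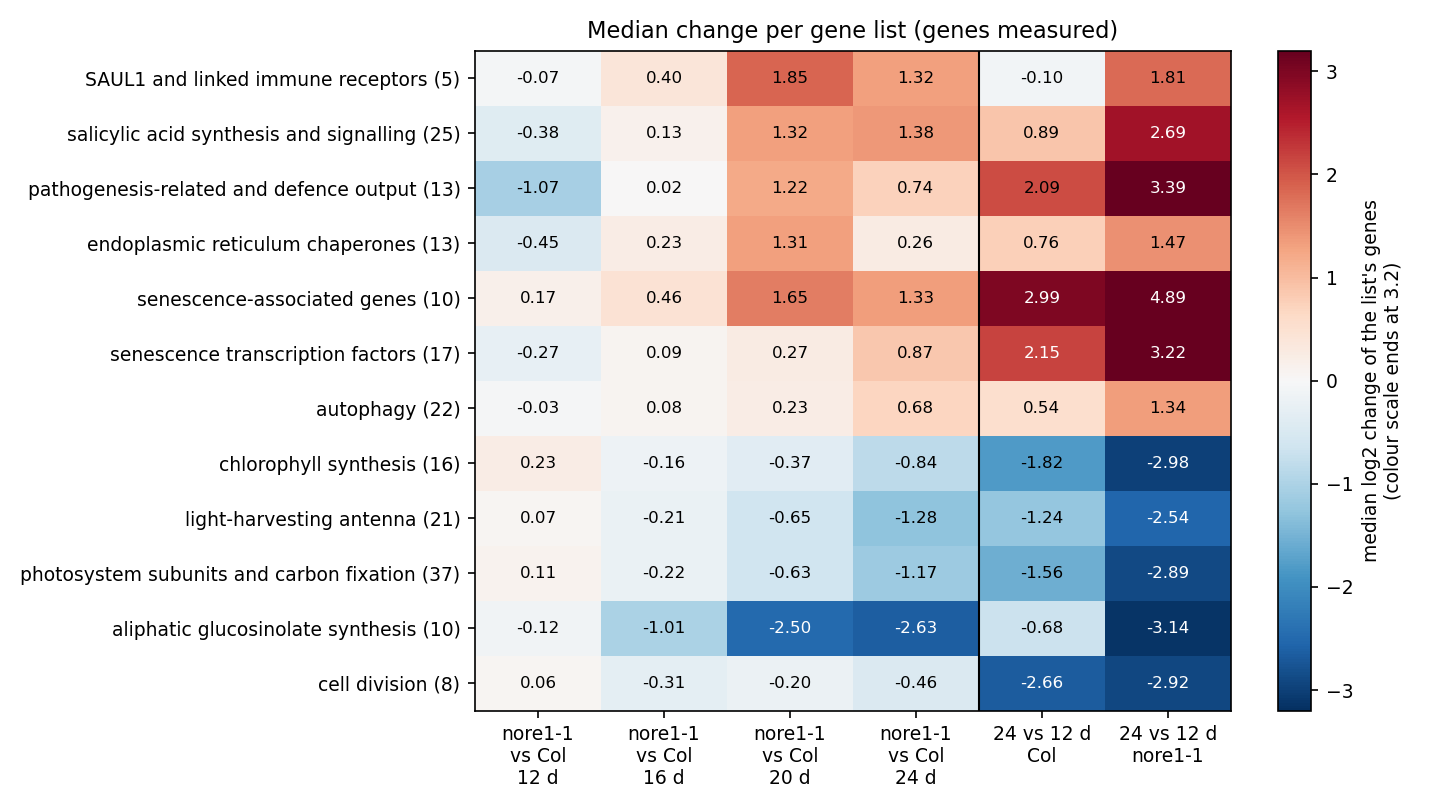
Median log2 fold change of 12 gene lists (rows) in 6 comparisons (columns), as colour that ends at 3.2 and as printed values. At 24 days against Col, photosystem genes had a median of -1.17 and autophagy genes 0.68, with the same sign under every scaling tried, whereas at 16 days the salicylic acid median of 0.13 turned to -0.01 with normexp and 75th percentile scaling.

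The average over the 4 ages, with 8 arrays of each genotype, gave the mean genotype difference, which need not be shared by the ages. The main fit took the arrays of a slide as independent. The gene AT3G05170 was higher by 5.67 ± 0.12 (adjusted p = 7.45e-09), with 1 Col array not well above background. AT3G55920 at 7.38 ± 0.22 (adjusted p = 4.51e-08) and AT3G55910 at 7.49 ± 0.22 (adjusted p = 4.51e-08) were not well above background on 5 and on all 8 Col arrays. With these arrays at the lowest signal above background the values were 7.13 and 5.15. Among genes above background on all arrays, the transcription factor gene NAC100 was higher by 3.07 ± 0.31 (adjusted p = 0.000740), GA2OX2 by 3.54 ± 0.46 (adjusted p = 0.00178), the ion channel gene CNGC19 by 2.93 ± 0.47 (adjusted p = 0.00373) and SWEET15 by 2.66 ± 0.44 (adjusted p = 0.00405). AT3G28899 was lower by -4.94 ± 0.21 (adjusted p = 1.16e-06), PDF1.2 by -4.0 ± 0.69 (adjusted p = 0.00500), MRD1 by -3.48 ± 0.38 (adjusted p = 0.000877), AT3G07170 by -2.46 ± 0.07 (adjusted p = 4.51e-08) and QQS by -2.36 ± 0.24 (adjusted p = 0.000663). AT3G56210 was lower by -2.96 ± 0.17 (adjusted p = 1.39e-05) on 1 of its 3 probes, and its difference was 0.46 in the authors' table. PAD4 was higher by 1.54 ± 0.26 (adjusted p = 0.00426) and ICS1 by 2.00 ± 0.34 (adjusted p = 0.00462), although they differed by -0.37 and -0.03 at 12 days.

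In all 4742 genes passed in the average, 2007 higher and 2735 lower, of which 1412 changed at least 2-fold. Photosystem genes fell in 20 of 37 cases, 23 adjusted over the list alone (median -0.45, adjusted p = 6.07e-09, and 0.570 with an estimated correlation). Antenna genes fell in 8 of 21, 12 adjusted over the list alone (-0.52, adjusted p = 0.000165, and 0.570 with an estimated correlation). Aliphatic glucosinolate genes fell in 9 of 10 cases, all 10 adjusted over the list alone (-1.60, adjusted p = 0.000157, and 0.570 with an estimated correlation). Chlorophyll synthesis fell in 5 of 16 genes, 5 lower and 1 higher adjusted over the list alone (-0.27, adjusted p = 0.0102, and 0.573 with an estimated correlation). Salicylic acid genes rose in 10 of 25 cases and fell in 1, 11 and 1 adjusted over the list alone (0.62, adjusted p = 0.000121, and 0.570 with an estimated correlation). Autophagy rose in 5 of 22 genes, also 5 adjusted over the list alone (0.18), and senescence-associated genes in 4 of 10, 5 adjusted over the list alone (0.67), each at an adjusted p of 0.00166, and 0.570 with an estimated correlation. SAUL1 and linked receptors rose in 3 of 5 cases, 4 adjusted over the list alone (0.88, adjusted p = 0.00760, and 0.570 with an estimated correlation). All 8 medians kept their sign on both scan days. In size, days 1 and 2 differed by over 1.5 times for 2 of 8 lists: chlorophyll synthesis -0.15 and -0.38, and autophagy 0.14 and 0.23.

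The list tests of the average were not repeated with slide as a block. With slide as a random block, since each slide held 1 genotype, 823 genes of the average passed, 419 higher and 404 lower, and all 823 were among the 4742. ICS1 then had an adjusted p of 0.0526 and SOC3 of 0.0668, the highest over all alternatives, of which the lowest were 0.000890 and 0.00258. The count was 2937 without Col at 12 days replicate 2, 3069 without Col at 16 days replicate 1, 3071 without nore1-1 at 16 days replicate 2 and 3103 without nore1-1 at 12 days replicate 1. Of 103 named genes called, leaving out 1 array ended between 5 calls (nore1-1 at 24 days replicate 1) and 26 (Col at 16 days replicate 1), with adjusted p up to 0.108. Median scaling called 2381 higher and 2099 lower, and normexp with 75th percentile scaling called 3043 and moved the median of all genes by 0.14.

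Next, 24 days were compared with 12 days in Col. SAG12, the protease gene used as a senescence marker, was at least 225-fold higher at 24 days by the mean of 2 arrays that lay far apart (log2 9.68 ± 2.46, adjusted p = 0.0126). Without Col at 24 days replicate 1 or 2 its log2 value was 4.94 or 14.41, the first not past the test. Nor did it pass without Col at 12 days replicate 2 (adjusted p = 0.0840), and over all alternatives its adjusted p lay between 0.000782 and 0.111. SWEET15 was 198-fold higher (log2 7.63 ± 0.87, adjusted p = 0.000292). CCD8, a gene of strigolactone synthesis, was at least 514-fold higher (log2 11.02 ± 1.34, adjusted p = 0.000368), the protease inhibitor gene KTI1 at least 902-fold (log2 10.41 ± 1.11, adjusted p = 0.000208), and the nitrilase gene NIT2 was higher by 11.56 ± 1.80, measured on 1 of 2 arrays at 12 days (adjusted p = 0.00112). AT3G61930 was at least 247-fold higher (log2 9.73 ± 1.45, adjusted p = 0.000905). Lower at 24 days were AT3G16670 by at least 1238-fold (log2 -12.16 ± 1.1, adjusted p = 0.000114), the germin-like gene GER3 by at least 463-fold (log2 -9.07 ± 1.13, adjusted p = 0.000413) and the desaturase gene ADS1 by at least 108-fold (log2 -9.02 ± 0.77, adjusted p = 9.32e-05). The expansin gene EXPA8, whose product loosens growing cell walls, fell by 7.57 ± 1.01 on the log2 scale (adjusted p = 0.000555), and the myrosinase gene TGG2 by -7.22 ± 0.61 (adjusted p = 9.24e-05). The senescence regulators ORE1 and NAP rose by 2.1 ± 0.52 (adjusted p = 0.0114) and 2.52 ± 0.52 (adjusted p = 0.00454), SAG13 by 5.99 ± 1.22 (adjusted p = 0.00441) and NYE1 by 2.58 ± 0.45 (adjusted p = 0.00185). PAD4 at 0.84 ± 0.51 (adjusted p = 0.233) and PR1 at 3.72 ± 1.7 (adjusted p = 0.115) did not pass.

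In all 7193 genes passed with age in Col, 3209 higher and 3984 lower, of which 5126 changed at least 2-fold, and 13 lists passed. Senescence transcription factors rose in 14 of 17 cases, 16 adjusted over the list alone, such as NAC019 by 3.83 ± 0.32 (adjusted p = 9.24e-05), with a median of 2.15 (adjusted p = 9.41e-08, and 0.468 with an estimated correlation). Senescence-associated genes rose in 9 of 10 cases, also 9 adjusted over the list alone (median 2.99, adjusted p = 8.41e-06, and 0.477 with an estimated correlation). Photosystem genes fell in 34 of 37 cases, also 34 adjusted over the list alone (-1.56, adjusted p = 9.34e-14, and 0.477 with an estimated correlation). Antenna genes fell in 14 of 21, 15 adjusted over the list alone (-1.24, adjusted p = 5.76e-06, and 0.504 with an estimated correlation). Chlorophyll synthesis fell in 14 of 16 genes, 15 adjusted over the list alone (-1.82, adjusted p = 1.91e-08, and 0.477 with an estimated correlation). Cell division fell in 7 of 8 genes, all 8 adjusted over the list alone, for example the cyclin gene CYCD3;1 by -4.09 ± 0.40 (adjusted p = 0.000154), with a median of -2.66 (adjusted p = 3.98e-05, and 0.477 with an estimated correlation). Abscisic acid genes rose in 11 of 19 cases, also 11 adjusted over the list alone, with the phosphatase gene HAI1 at 6.21 ± 0.51 (adjusted p = 8.54e-05) and a median of 0.86 (adjusted p = 0.000336, and 0.504 with an estimated correlation). Salicylic acid genes rose in 7 of 25 cases, also 7 adjusted over the list alone (0.89, adjusted p = 0.00306, and 0.551 with an estimated correlation). Pathogenesis-related genes rose in 4 of 13, also 4 adjusted over the list alone (2.09, adjusted p = 0.00729, and 0.551 with an estimated correlation). Autophagy rose in 9 of 22 genes, also 9 adjusted over the list alone (0.54, adjusted p = 0.00432, and 0.498 with an estimated correlation). Phloem and xylem markers fell in 5 of 10 cases and rose in 1, 6 and 1 adjusted over the list alone, such as the xylem protease gene XCP1 by -4.63 ± 0.82 (adjusted p = 0.00211), with a median of -2.44 (adjusted p = 0.0260, and 0.504 with an estimated correlation).

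Heat shock genes rose in 5 of 11 cases in Col, 6 higher and 1 lower adjusted over the list alone, with a median of 1.03 that was -0.06 with normexp and 75th percentile scaling (adjusted p = 0.0382, and 0.477 with an estimated correlation). With the genes that had only a bound set at it, that median was 0.79. Ethylene genes rose in 7 of 17 cases and fell in 2, 8 and 2 adjusted over the list alone (0.64, adjusted p = 0.0403, and 0.490 with an estimated correlation). All 13 medians kept their sign on both scan days. Between days 1 and 2 the medians were over 1.5 times apart for 2 of 13 lists: antenna genes -1.59 and -0.76, and salicylic acid 1.09 and 0.59. With scan day as a block, the ethylene list no longer passed (adjusted p = 0.0528). The count was 3328 without Col at 12 days replicate 2, where 38 of 106 named genes lost the call, and 33 lost it without Col at 24 days replicate 1, at most 6 without any other array (adjusted p up to 0.109). It was 3630 with normexp and 75th percentile scaling and 3741 with only the arrays of the groups compared.

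The same comparison was made in nore1-1. PR1 rose by 10.98 ± 1.7, measured on 1 of 2 arrays at 12 days (adjusted p = 0.000271), PAD4 by 3.56 ± 0.51 (adjusted p = 0.000174) and ICS1 by 4.31 ± 0.68 (adjusted p = 0.000308). SAG12 rose by 13.26 ± 2.46, also measured on 1 of 2 arrays at 12 days (adjusted p = 0.000902), SWEET15 was 1504-fold higher (log2 10.55 ± 0.87, adjusted p = 7.25e-06), and DIN2 at least 5479-fold higher (log2 13.51 ± 1.12, adjusted p = 7.32e-06). CCD8 was at least 3620-fold higher (log2 13.88 ± 1.34, adjusted p = 1.48e-05), and the membrane protein gene DMP1 rose by 9.63 ± 1.2 (adjusted p = 6.52e-05). EXPA8 was 2906-fold lower (SE 1.01 on the log2 scale, adjusted p = 9.51e-06), AT3G16670 was at least 3732-fold lower (adjusted p = 6.45e-06), GASA6 was lower by -9.31 ± 0.71 (adjusted p = 5.21e-06) and FLA2, a cell wall protein gene, by -9.17 ± 0.65 (adjusted p = 4.05e-06). Of the 15 genes named in advance with SAUL1, 14 passed and SAUL1 did not.

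In all 12733 genes passed with age in nore1-1, 6076 higher and 6657 lower, of which 9737 changed at least 2-fold, and 16 lists passed. All 37 photosystem genes fell, also adjusted over the list alone, such as PRK by -3.65 ± 0.21 (adjusted p = 2.10e-06), with a median of -2.89 (adjusted p = 7.20e-13, and 0.413 with an estimated correlation). Antenna genes fell in 21 of 21 cases, also adjusted over the list alone (-2.54, adjusted p = 2.14e-06, and 0.439 with an estimated correlation). Chlorophyll synthesis fell in 15 of 16, also 15 adjusted over the list alone (-2.98, adjusted p = 8.28e-07, and 0.413 with an estimated correlation). Salicylic acid genes rose in 22 of 25 cases and fell in 1, 23 and 1 adjusted over the list alone, with FMO1 at 7.95 ± 1.34 (adjusted p = 0.000486) and a median of 2.69 (adjusted p = 2.47e-06, and 0.439 with an estimated correlation). Pathogenesis-related genes rose in 12 of 13 cases, also 12 adjusted over the list alone (3.39, adjusted p = 0.000478, and 0.439 with an estimated correlation). Receptors rose in 11 of 18 cases and fell in 1, also 11 and 1 adjusted over the list alone (0.81, adjusted p = 0.0169, and 0.439 with an estimated correlation). Senescence transcription factors rose in 16 of 17 cases, also 16 adjusted over the list alone (3.22, adjusted p = 2.14e-06, and 0.413 with an estimated correlation). Senescence-associated genes rose in 9 of 10, also 9 adjusted over the list alone (4.89, adjusted p = 0.000233, and 0.413 with an estimated correlation). Autophagy rose in 16 of 22 genes, 17 adjusted over the list alone (1.34, adjusted p = 2.22e-05, and 0.413 with an estimated correlation). Nitrogen remobilisation rose in 9 of 12 with 2 lower, also 9 and 2 adjusted over the list alone (2.18, adjusted p = 0.0237, and 0.413 with an estimated correlation).

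Of the other lists with age in nore1-1, cell division fell in 8 of 8 genes, also adjusted over the list alone (median -2.92, adjusted p = 0.00216, and 0.439 with an estimated correlation). Aliphatic glucosinolates fell in 9 of 10, all 10 adjusted over the list alone (-3.14, adjusted p = 0.0169, and 0.581 with an estimated correlation). Abscisic acid genes rose in 12 of 19 cases, also 12 adjusted over the list alone (1.11, adjusted p = 0.0126, and 0.581 with an estimated correlation). SAUL1 and linked receptors rose in 4 of 5, also 4 adjusted over the list alone (1.81, adjusted p = 0.0345, and 0.439 with an estimated correlation). Heat shock rose in 7 of 11 genes, also 7 adjusted over the list alone (1.7, adjusted p = 0.0171, and 0.413 with an estimated correlation), or a median of 1.34 with bound genes at their bound. Endoplasmic reticulum chaperones rose in 3 of 13 cases, 2 adjusted over the list alone (1.47, adjusted p = 0.0282, and 0.581 with an estimated correlation). Cell type markers did not pass as lists: phloem and xylem had 7 of 10 lower and 1 higher (-3.01, adjusted p = 0.0696), epidermis and trichomes 4 of 6 lower (-2.58, adjusted p = 0.143), and guard cells 2 of 5 lower and 1 higher (-0.76, adjusted p = 0.308). All 16 medians kept their sign on both scan days. On days 1 and 2 the medians lay over 1.5 times apart for 4 of 16 lists: aliphatic glucosinolates -1.54 and -4.83, heat shock 2.58 and 1.34, abscisic acid 1.27 and 0.68, and senescence transcription factors 2.49 and 3.93. Median scaling called 7526 higher and 5508 lower against 6076 and 6657, and moved the median of all genes by 0.30; quantile normalization moved it by 0.10, and keeping dim probes moved it by -0.15. Of 135 named genes at most 9 lost the call without 1 array, nore1-1 replicate 2 at 12 or at 24 days (adjusted p up to 0.368).

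Whether the change from 12 to 24 days differed between the genotypes was tested directly. It was larger in nore1-1 for PAD4 by 2.72 ± 0.73 (adjusted p = 0.0394), NYE1 by 2.37 ± 0.63 (adjusted p = 0.0384) and SOC3 by 2.08 ± 0.56 (adjusted p = 0.0396), whereas ICS1 at 3.10 ± 0.96 (adjusted p = 0.0594) and PR1 at 7.25 ± 2.40 (adjusted p = 0.0714) did not pass. ALD1, which makes an immune signal from lysine, differed by 6.03 ± 1.61 (adjusted p = 0.0391), BFN1 by 5.89 ± 1.54 (adjusted p = 0.0370), DMP1 by 6.26 ± 1.69 (adjusted p = 0.0407) and ADPG1 by 7.63 ± 2.22 (adjusted p = 0.0496), or 6.96 with arrays not above background at the lowest signal above it. AT1G52190 differed by -6.90 ± 0.94 (adjusted p = 0.0116), AACT1 by -6.69 ± 1.35 (adjusted p = 0.0192) and PKS4, a light signalling gene, by -5.28 ± 0.98 (adjusted p = 0.0170). In all 2582 genes passed, 1001 with a more positive and 1581 with a more negative change in nore1-1.

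Of the lists 12 passed for this difference. Photosystem genes had 17 of 37 more negative, 26 adjusted over the list alone, for example PRK by -1.79 ± 0.30 (adjusted p = 0.0147), with a median of -1.27 (adjusted p = 1.90e-10, and 0.471 with an estimated correlation). Autophagy had 6 of 22 more positive, 9 adjusted over the list alone, with ATG8H at 2.75 ± 0.46 (adjusted p = 0.0147) and a median of 0.81 (adjusted p = 4.11e-06, and 0.471 with an estimated correlation). Salicylic acid genes had 5 of 25 more positive, 10 adjusted over the list alone, with CBP60G at 3.06 ± 0.75 (adjusted p = 0.0317) and a median of 1.83 (adjusted p = 1.22e-06, and 0.471 with an estimated correlation). Chlorophyll synthesis had 6 of 16 more negative, 9 adjusted over the list alone (-1.01, adjusted p = 0.000124, and 0.471 with an estimated correlation). Antenna genes had 2 of 21, 9 adjusted over the list alone (-1.36, adjusted p = 0.000124, and 0.582 with an estimated correlation). Pathogenesis-related genes had 3 of 13 more positive, 4 adjusted over the list alone (1.52, adjusted p = 0.00145, and 0.581 with an estimated correlation). Senescence transcription factors had 2 of 17, 3 adjusted over the list alone (1.32, adjusted p = 0.00199, and 0.471 with an estimated correlation). Receptors had 2 of 18 more positive and 1 more negative, 5 and 1 adjusted over the list alone (0.63, adjusted p = 0.0153, and 0.471 with an estimated correlation). SAUL1 and linked receptors had 1 of 5 more positive, 3 adjusted over the list alone (1.38, adjusted p = 0.0156, and 0.471 with an estimated correlation). Senescence-associated genes had 1 of 10, 2 adjusted over the list alone (1.39, adjusted p = 0.0456, and 0.582 with an estimated correlation). Nitrogen remobilisation had 2 of 12 more positive and 1 more negative, also 2 and 1 adjusted over the list alone (1.18, adjusted p = 0.0411, and 0.471 with an estimated correlation). Aliphatic glucosinolates had 0 of 10 called and 0 adjusted over the list alone by limma, where 6360 of all genes had an unadjusted p under 0.05, with a median of -2.44 (adjusted p = 0.00731, and 0.685 with an estimated correlation). Cell type markers did not pass as lists. Epidermis and trichomes had 1 of 6 more negative, 3 adjusted over the list alone (-1.52, adjusted p = 0.268). Phloem and xylem had 0 of 10 called (-0.48, adjusted p = 0.716) and guard cells 0 of 5 (-0.42, adjusted p = 0.708). All 12 medians of the lists that passed kept their sign on both scan days. Over 1.5 times apart on days 1 and 2 were the medians of 9 of 12 lists: antenna genes -0.57 and -1.91, nitrogen remobilisation 0.61 and 1.47, receptors 0.40 and 0.93, aliphatic glucosinolates -1.44 and -3.28, and photosystem genes -0.80 and -1.75. The rest of these were salicylic acid 1.17 and 2.56, SAUL1 and linked receptors 0.92 and 1.85, chlorophyll synthesis -0.72 and -1.38, and pathogenesis-related genes 1.13 and 2.03. With scan day as a block, nitrogen remobilisation no longer passed (adjusted p = 0.0634) and chlorophyll breakdown passed (adjusted p = 0.0346).

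The count for this difference was 6 without Col at 12 days replicate 1, 10 without nore1-1 at 12 days replicate 2, 289 without Col at 24 days replicate 2 and 484 without nore1-1 at 24 days replicate 2. It was 833 without nore1-1 at 12 days replicate 1, 1343 without Col at 12 days replicate 2, 1492 without either nore1-1 array at 16 days, and 4441 without Col at 24 days replicate 1. Of 52 named genes called, the first 4 of these arrays ended 50, 50, 38 and 37 calls and each array ended at least 1. PAD4 had an adjusted p of 0.138 without Col at 12 days replicate 1, and over all alternatives its adjusted p lay between 0.0105 and 0.138. Normexp with 75th percentile scaling called 257 genes, keeping dim probes 1441, only the arrays of the groups compared 3, scan day as a block 4582, slide as a fixed block 4005 and slide as a random block 4423. Median scaling called 1372 more positive and 1041 more negative and the values of the authors 1505 and 1539, against 1001 and 1581. Median scaling moved the median of all genes by 0.21.

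The change with age in Col was set against the genotype difference at each age. Across 20531 genes, which are not independent replicates, the Pearson correlation was 0.509 at 20 days and 0.25 at 16 days, comparisons that share no array, against simulated values of 0.00 for unchanged groups. Within replicates 1 and 2 it was 0.451 and 0.427 at 20 days and 0.280 and 0.119 at 16 days. The difference at 24 days, which shares the Col arrays of that age with opposite sign, correlated at 0.419 against a simulated -0.499, with a covariance of 0.725 against a simulated -0.10. For 12 days the correlation was -0.179 against a simulated 0.502, with a covariance of -0.10 against a simulated 0.10. Of the genes called at 20 days, 408 were higher and 758 lower in both comparisons, where independent lists would share 143 and 262, and 70 went opposite ways. At 24 days 1007 were higher and 1521 lower in both, where independent lists would share 427 and 703, and 357 went opposite ways. At 24 days PRK was lower and NAC019 higher in both. With normexp and 75th percentile scaling the correlation was 0.543 at 20 days and -0.01 at 16 days. Leaving out 1 array it lay between 0.409 and 0.561 at 20 days, and between 0.0658 and 0.372 at 16 days.

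**Figure D4:**
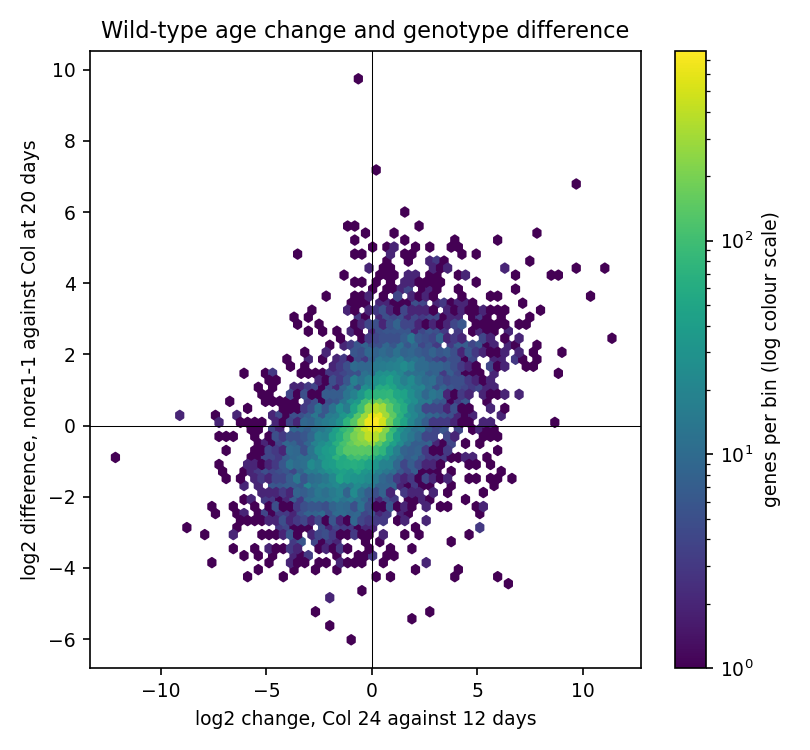
Log2 change from 12 to 24 days in Col (x axis) against the log2 difference of nore1-1 from Col at 20 days (y axis), with 20531 genes as hexagons shaded by their number. The Pearson correlation across genes is 0.509, and genes are not independent replicates.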

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

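The test of the difference between the age changes was planned, whereas reading the probes without a locus as a separate set was chosen after the data were seen, as was raising signals not above background. The change from 12 to 24 days differed between nore1-1 and Col for 2582 genes by a test of the difference itself, with n = 2 arrays per group. The count was 6 without Col at 12 days replicate 1, 10 without nore1-1 at 12 days replicate 2, 3 with only the arrays compared and 257 with normexp and 75th percentile scaling. The change was more positive in nore1-1 for AT3G55910 by 8.50, AT1G29100 by 8.27, ARD3 by 8.00, ADPG1 by 7.63, scpl14 by 7.53, DMP1 by 6.26, ALD1 by 6.03, AT3G25950 by 5.94, BFN1 by 5.89 and AT4G11655 by 5.66 on the log2 scale. PAD4 differed by 2.72, NYE1 by 2.37 and SOC3 by 2.08. ADPG1 no longer passed in 18 of 28 alternatives, ARD3 in 16 of 28, SOC3 in 16 of 29, and PAD4, NYE1, ALD1 and BFN1 each in 14 of 29. More negative were AT1G52190 at -6.90, AACT1 at -6.69, AT5G14920 at -5.91, AT5G22580 at -5.86, AT5G01075 at -5.85, PKS4 at -5.28 and RTFL21 at -5.23. Some arrays were not well above background for AT3G55910 (all 8 Col arrays), AT1G29100, ARD3, ADPG1, scpl14, AT5G22580 and AT5G01075, so these values are not exact. With those arrays at the lowest signal above background they were 8.50, 7.52, 7.01, 6.96, 5.95, -5.86 and -4.77.

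Gene lists differed in the same test by their median. Positive medians were found for SAUL1 and linked receptors at 1.38, salicylic acid at 1.83, pathogenesis-related genes at 1.52, immune receptors at 0.63, senescence transcription factors at 1.32, senescence-associated genes at 1.39, autophagy at 0.81 and nitrogen remobilisation at 1.18. Negative medians were found for aliphatic glucosinolates at -2.44, chlorophyll synthesis at -1.01, antenna genes at -1.36 and photosystem genes at -1.27. None of the 12 passed with an estimated correlation, and 9 had medians over 1.5 times apart on the 2 scan days, such as antenna genes at -0.57 and -1.91. No technical or biological explanation of these differences was tested beyond the alternatives, and slide and genotype are joined in the design.

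Of 5235 tested probes not matched to a locus, 698 passed at 24 days, 220 higher and 478 lower in nore1-1. That is 13.3%, against 30.9% of the genes. Whether they measure anything apart from the matched genes was not tested.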

How the results depend on the processing

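All alternatives were planned, except that normexp used the median spot signal. The counts moved as follows, and the cause was not tested, except that leaving out arrays or groups lowers the degrees of freedom. With quantile normalization 8 genes passed at 12 days. With normexp and 75th percentile scaling 5886 passed at 16 days, 904 at 20 days, 3107 at 24 days, 3043 in the average, 3630 with age in Col and 257 in the difference between changes. There CYCD3;1 at 1.60, CDKB2;1 at 1.77, AG at 1.77, SEP3 at 1.80 and COBL9 at 2.38 reversed at 16 days, SEP3 at 0.31 in the average and HSP21 at -0.25 with age in Col, and the correlation with age was -0.01 at 16 days (-0.0095) and 0.543 at 20 days. With normexp and quantile normalization 13 passed at 12 days and the correlation at 20 days was 0.536. Without a filter 1441 passed in the difference between changes and that correlation was 0.458. With the filter on all 16 arrays 3 passed at 16 days. With the values of the authors 11 genes passed at 12 days. There AT3G56210 reversed to 0.23 at 12 days, 0.37 at 16 days and 0.46 in the average. With trend and robust 9 passed at 12 days. With only the arrays of the groups compared limma called 0 at 12 and 0 at 16 days, where the full fit had 571 and 528 unadjusted p under 0.05, and 3 at 20 days, 1 at 24 days, 3741 with age in Col and 3 in the difference. Slide as a fixed block gave 4005 and as a random block 4423 in the difference, and as a random block 823 in the average.

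With the replicate number as a block 8 genes passed at 12 days, 3723 at 20 days and 4582 in the difference between changes. Of the calls without it, 2266 of 2268 at 20 days and all 2582 in the difference were shared. Of the 240 list tests 4 no longer passed and 1 newly passed. Deviations of same-numbered arrays correlated between -0.146 and 0.594 over 28 pairs of groups, above 0.1 in 20. Pairing was to be taken only where all pairs exceeded 0.1, and the replicate number equals the scan day.

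Leaving out 1 array, with the lone array of a group assumed to vary like the other groups, gave 4 to 7 calls at 12 days, 5 to 9 at 16 days, 78 to 3028 at 20 days, 2240 to 6928 at 24 days, 2937 to 5938 in the average, 3328 to 7353 with age in Col, 10457 to 12914 with age in nore1-1 and 6 to 4441 in the difference. The correlation lay between 0.0658 and 0.372 at 16 days and between 0.409 and 0.561 at 20 days. Named genes gave 31836 recomputed values, 18096 of them from fits without 1 array. Where the group of that array was not compared, the log2 value could not move, so its direction was bound to be kept. A gene called in neither fit also counted as kept. Of the 31836 values 10 reversed, 1808 no longer passed, 524 newly passed and 29494 kept direction and side of the threshold. These last include values that passed in neither fit and differed in sign, 57 with normexp and 75th percentile scaling and 173 over the left-out arrays. Of 240 list tests 88 no longer passed with an estimated correlation. These were all the passing tests, so no list passed then. Estimated correlations between the genes of a list ran from -0.0904 (flower organ markers) to 0.921 (aliphatic glucosinolates), against the preset 0.01. With fry 35 of the 240 no longer passed and 25 newly passed. Leaving out 1 array moved 18 of 42 called named genes by over 1.5 times at 20 days, 46 of 92 at 24 days, 1 of 103 in the average, 49 of 106 with age in Col, 62 of 135 with age in nore1-1 and 27 of 52 in the difference. Signal over background limits dim genes: folds are bounds only where both arrays of a group were dim, and uncertain where some arrays were.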

Other observations

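The tests on neighbouring genes, on scan day, of lists at 16 and 20 against 12 days and of groupings that keep scan days balanced or slides whole were chosen after the results were seen. The splits that keep ages balanced and the test of the shared Col arrays were chosen before. At the ages between, nore1-1 leaves had higher defence genes at 16 than at 12 days: 5 of 25 salicylic acid genes rose (median 1.52, adjusted p = 1.38e-08, and 0.309 with an estimated correlation) and 5 of 13 pathogenesis-related genes (2.46, adjusted p = 7.93e-08, and 0.309 with an estimated correlation). In Col over the same days limma called 0 of all genes, where 2207 had an unadjusted p under 0.05, and both lists passed too, salicylic acid at 0.49 (adjusted p = 1.59e-05, and 0.513 with an estimated correlation) and pathogenesis-related genes at 1.31 (adjusted p = 2.23e-05, and 0.482 with an estimated correlation). The difference between these changes was also called for 0 genes by limma, with 275 unadjusted p under 0.05, a smaller share than the 0.05 that unchanged genes would give. As lists these changes differed by 0.86 (adjusted p = 3.83e-07) and 1.09 (adjusted p = 3.79e-06), each 0.591 with an estimated correlation, while at 16 days itself the pathogenesis-related median differed by 0.02 (adjusted p = 0.381). From 12 to 20 days all 13 endoplasmic reticulum chaperones, which fold secreted proteins, rose in nore1-1 (median 2.38, adjusted p = 0.000278, and 0.435 with an estimated correlation). In Col 0 of 13 were called by limma, where 7109 of all genes had an unadjusted p under 0.05 (median 0.76, adjusted p = 0.0739). The difference between these changes was called for 30 of 20531 genes and 0 of the 13, with 4138 unadjusted p under 0.05 in limma, and had a list median of 1.63 (adjusted p = 5.63e-05, and 0.530 with an estimated correlation). In Col 14 of 17 senescence transcription factors rose over these days (median 1.91, adjusted p = 4.83e-09, and 0.318 with an estimated correlation), and 9 of 23 jasmonate genes (1.02, adjusted p = 7.37e-05, and 0.465 with an estimated correlation). In nore1-1 also 14 of 17 of these factors rose (median 2.61, adjusted p = 5.15e-06, and 0.350 with an estimated correlation), while of jasmonate genes 9 of 23 were higher and 1 lower (0.50, adjusted p = 0.0946).

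The genotype average called 4742 genes. Of 100 splits that kept ages balanced, 2 called as many, the real one included, and of all 128 splits that kept ages and scan days balanced, 3 did. Few exchanges of single arrays thus called as many genes. Such exchanges break up the slides, so they cannot exclude chance differences between slides. The highest other split called 6341 genes, which points to a structure of the samples: it kept the genotypes apart at 20 and 24 days and exchanged 1 array at 12 and at 16 days. With scan days balanced, the highest other split called 5323 genes. After the group means were fitted, the residuals of arrays on a slide correlated at 0.230. Whole slides give only 3 groupings, too few for a share under 0.05. Of these 1 called as many, the real one itself, and the highest other called 1214 (the split by scan day). Slide as a random block called 823.

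Runs of neighbouring genes differed between the genotypes at 12 and 16 days: in windows of 7 genes the highest absolute median was 1.02, against 0.676 in the highest of 100 shuffled orders, and 3 runs lay past it. On chromosome 1, 13 genes from AT1G10230 to AT1G10380 were all higher in nore1-1 at those ages (median 0.95) and 4 from AT1G65690 to AT1G65720 lower (-1.04, but -0.24 at 20 and -0.31 at 24 days), and on chromosome 3, 5 genes from AT3G22300 to AT3G22360 were higher (0.89). For the 2 higher runs only, the lowest median in a slide pair at 20 and 24 days was 0.827, which argues against a single slide or scan day. The 8 other probes of their genes, which did not choose the runs, 7 on chromosome 1 and 1 on chromosome 3, had a median of 0.948, but the files give no probe sequences, so overlap is unknown and sequence differences stay open. A doubled copy number may account for the higher run on chromosome 1, whose median at 20 and 24 days lay within 0.173 of 1 log2 unit, although GSTU18 at -0.03 and -0.29, AT1G10380 at -0.24 and -1.44 and AT1G10340 at 3.35 and 3.06 lay far from it then, and stays open for that on chromosome 3, where the slide pairs had 1.04 and 1.49 (up to 0.491 from 1), and no DNA was analysed.

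At 12 days the genotype difference ran against the wild-type ageing direction. Its correlation across genes, which are not independent replicates, with the Col change from 16 to 20 days was -0.185, and these share no array. With the Col change from 12 to 24 days, which shares the Col arrays at 12 days, it was -0.179. Sharing these arrays gave a positive 0.502 in simulated unchanged groups. Both values argue against the shared Col arrays as a cause of the negative sign. The higher of the values on the 2 scan days was -0.154, which argues against a single scan day. With the difference from scan day 1 and the ageing direction from day 2 the value was -0.139, and the other way round a weaker -0.0819. A slightly younger stage of nore1-1 leaves at 12 days may underlie the negative correlation, and it was not tested in another way.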
